A study of Mus musculus with 14 samples.

How the data were processed

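The series examined BMI1 and H2AK119ub by ChIP-seq in Sca1+CD45- cells enriched by magnetic sorting from mouse heart, after paraquat (Damage) or PBS (Homeostasis). Per the labels' protocols, cells were crosslinked with formaldehyde, chromatin was sonicated, a slurry of protein A agarose with salmon sperm DNA was used to preclear the lysate and to collect the antibody complexes, and libraries were made with a NEBNext kit. The labels also describe culture of the cells at 3% oxygen, without saying whether the cells used for ChIP-seq had been cultured. Per the submitters' processing notes, the tools were Bowtie2, without a version, and HOMER version 4.8, and the genome build was GRCm38. The peak-calling settings, the thresholds and the use of the Input libraries are not given in the sources used here.

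The authors deposited a list of peaks for each of the 12 ChIP libraries, so peaks were listed per library and not on pooled replicates. Each list gives the position of each peak and a score column, and the deposited score is 1 for every peak of every list, so it ranks nothing. Most peaks were 101 bp wide (92.6% or more of each list), and none was wider than 201 bp. A number at the end of the deposited peak names, 1 or 2, gave the count of peaks merged into the entry, per the form of the names. No reads, fragment counts or signal tracks were used here. Depth per library is therefore unknown, a peak number cannot be scaled for it, and binomial intervals (exact, 95%) cover only the counting of peaks. Peaks on sequences outside the assembled chromosomes (143 of 39832) were kept in peak numbers and left out of random placement and gene counts.

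Groups came from the treatment and antibody in the sample labels, with 3 libraries in each of 4 groups. The 2 Input libraries are labelled as untreated and were not analysed here. Peaks per library and covered length were compared on the log10(value + 1) scale by two-sided exact permutation tests, within an antibody (20 arrangements) and over both antibodies with treatment permuted within antibody (400 arrangements). Folds are ratios back-transformed from that scale. Replicate overlap, overlap of BMI1 with H2AK119ub and overlap of damage with homeostasis peaks used a minimum of 1 bp. Each was compared with 1000 placements of the same widths at random positions on the same chromosome, within the range spanned by the peaks and genes of the chromosome, for which the smallest p is 0.001. Consensus regions were merged peaks with 2 or more of 3 libraries.

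Genes came from a RefSeq table of GRCm38 with 49943 annotated genes, of which 21887 are protein-coding. The table gives gene boundaries without transcription start sites, exons or sequence. The classes planned for peak location (promoter, exon, intron) were therefore replaced by the share of peak centres in gene bodies, and windows around start sites by windows around both gene ends. Peak location was compared between treatments over libraries with 20 or more peaks, which left out Damage BMI1 replicate 1. A gene was counted when a peak lay in the gene body or within 5 kb on either side. The 14 fixed lists named 391 symbols, all of which matched the table. At homeostasis, list members with a peak in 2 or more libraries were compared with 10000 random lists drawn from protein-coding genes of the same length class (10 classes), with Benjamini-Hochberg adjustment over 28 tests (two-sided, smallest p 0.0002). Members with a peak per library were compared between treatments by the stratified exact permutation test, adjusted over the 14 lists.

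The gene lists, the tests and the rule for naming genes were chosen before the data were examined. The rule named damage regions found in 2 or more libraries of an antibody, and the widest peak of each Damage library. It also named 25 protein-coding genes per antibody among those with a peak in all 3 homeostasis libraries, up to 4 members of each list, and Cdkn2a and Bmi1 whatever their values. The 25 genes were those with the highest mean, over libraries, of the within-library percentile of summed peak width. Ranking by score was planned for lists that hold a score; since the score is constant, the rule's fallback of peak width was used. Of the genes selected by the rule, 1 is not reported here. Rb1 was named after its value was seen, as the sole list member with a peak after damage. Alternatives were the overlap rule, placement on any chromosome, merging of peaks within 1 kb, autosomes only, no log scale, the consensus rule, the gene window, Fisher's exact test for the lists, the replicate number as a block and leaving out each library in turn. Lists without peaks in the immunoglobulin heavy chain locus (Igh) and on tRNA and 5S genes were added as an alternative after the data were seen. Alternatives that filter on the score were not run.

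Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 and fixed random seeds. The procedures were tested on simulated data. In 2 simulated lists the size of Homeostasis BMI1 replicate 1, a planted overlap of 10% was recovered as 10.04% and 50% as 50%, and none planted gave 0.0399% (permutation p = 0.562). Random peaks gave 0 of 14 lists with p under 0.05, and 20 HOX genes given a peak were all recovered. A test of peak density per gene was run on 21887 genes, with 5 regions each added to 200 genes of 200 kb or more. It called 79 of these 200. It called no other gene, with genes that overlap a gene with added regions left out of that count.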

Results

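BMI1 and H2AK119ub were mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in Sca1+CD45- cells of the heart of C57BL/6 mice aged 6 to 8 weeks. BMI1 is a subunit of Polycomb repressive complex 1, and H2AK119ub is histone H2A carrying a single ubiquitin, the mark that complexes of this family place. Sca1 is a surface antigen used to enrich stromal and progenitor-type cells, and selection against CD45 removes leukocytes. Mice of the Damage group were given a single intraperitoneal dose of 20 mg/kg paraquat, a herbicide that produces superoxide by redox cycling, and mice of the Homeostasis group were given PBS. Each of the 4 combinations of treatment and antibody had 3 libraries, so 12 peak lists with 39832 peaks in total were compared. The 2 Input libraries of the series were not analysed here. The lists hold positions on GRCm38 and a score that is 1 for every peak, so the read depth of each library is unknown. The labels do not say whether the replicates came from separate mice, so p-values that compare libraries measure only the spread between these samples, which may be technical. P-values from random placement, random gene lists or counts of genes take peaks or genes as units. They measure no spread between libraries.

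The first question was how many regions each antibody marked after paraquat and after PBS. Damage lists held 217 peaks in all and Homeostasis lists 39615. For BMI1 the Damage libraries had 31.0 ± 14.4 peaks (SD, n = 3, range 19 to 47), against 5535 ± 1777 in the Homeostasis libraries (n = 3, range 4072 to 7513). For H2AK119ub the Damage libraries had 41.3 ± 23.3 peaks (n = 3, range 25 to 68), against 7670 ± 5745 at homeostasis (n = 3, range 2000 to 13487). Every Damage library lay below every Homeostasis library of its antibody, as the plot of peaks per library shows. On the log10(peaks + 1) scale the mean fell by 2.25 ± 0.136 (SE) for BMI1, a 179-fold difference, and for H2AK119ub it fell by 2.18 ± 0.277, a 152-fold difference. Over both antibodies the difference was 165-fold, and a two-sided exact permutation test within antibody gave p = 0.005, the smallest value its 400 arrangements allow. Like the other tests over both antibodies, it takes the BMI1 and H2AK119ub libraries as independent. Whether they shared chromatin is not known here. Within a single antibody, 3 libraries against 3 cannot give an exact two-sided p under 0.1, and both antibodies gave exact p = 0.1. The covered length, which takes peak width into account, was 1.92 to 6.93 kb per Damage library and 202 to 1371 kb per Homeostasis library, a 130-fold difference on the log10(kb + 1) scale (exact permutation p = 0.005). On the raw scale the fold was 183 for covered length and also for peak number. The drop did not differ detectably between antibodies: the ratio of the BMI1 to the H2AK119ub fold was 1.17 (exact permutation p = 0.825), and it lay below 1 when any of 4 single libraries was left out, with its lowest value of 0.685 without Homeostasis H2AK119ub replicate 1. The H2AK119ub fold was 261 without Homeostasis replicate 1 and 101 without Homeostasis replicate 2.

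**Figure D1:**
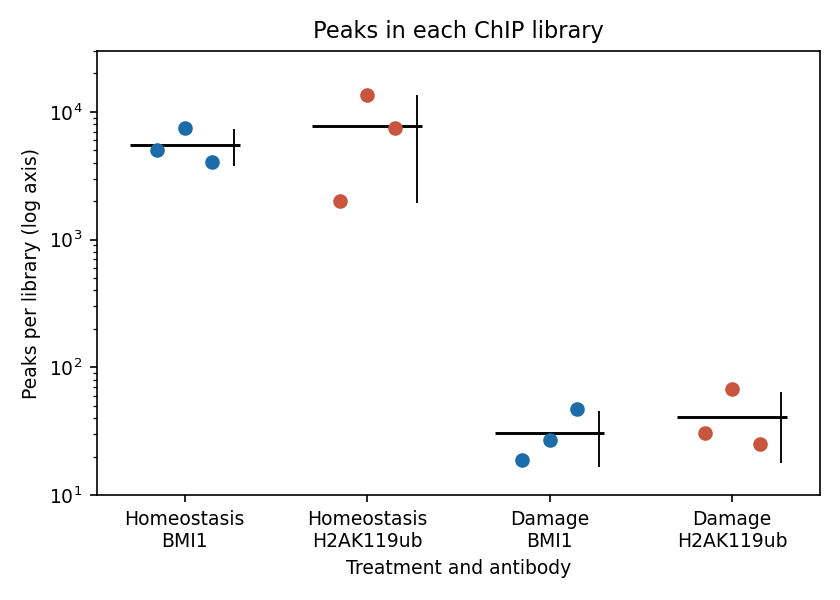
Peaks per library on a log10 axis for each treatment and antibody, with 1 point per library and the group mean ± SD (n = 3). The Damage libraries held 19 to 68 peaks and the Homeostasis libraries 2000 to 13487.

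Libraries of the same group were then compared with each other, to see how far a list was found again in its replicates. At homeostasis, a mean of 70.7 ± 13.8% (SD, n = 3) of the BMI1 peaks of a library overlapped a peak of another BMI1 replicate by 1 bp or more, and 72.3 ± 22.5% of the H2AK119ub peaks did. After damage the shares were 18.2 ± 6.89% for BMI1 and 13.3 ± 5.79% for H2AK119ub. Peaks of the same widths placed at random on the same chromosomes overlapped in 0.113% or less on average in every library, and each library lay above all of its 1000 placements (permutation p = 0.001, the smallest they can give). Regions with peaks in 2 or more of 3 libraries numbered 4478 of 9822 for BMI1 and 6341 of 15083 for H2AK119ub at homeostasis. After damage they numbered 7 of 84 for BMI1 and 7 of 116 for H2AK119ub. Regions in all 3 libraries numbered 2295 and 1567 at homeostasis, and 2 and 1 after damage. The damage shares rested on few peaks: without replicate 2 they were 7.39% for BMI1 and 3.61% for H2AK119ub, and without replicate 3 of H2AK119ub the latter was 7.05%. The homeostasis H2AK119ub share was 46.9% without replicate 3.

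The next question was whether the protein and the histone mark occupied common sites at homeostasis. Of the 4478 BMI1 regions, 3767 (84.1%) overlapped an H2AK119ub region. In the other direction, 3765 of the 6341 H2AK119ub regions (59.4%) overlapped a BMI1 region. Random placement gave 0.0576% and 0.0394%, and both shares lay above all 1000 placements (permutation p = 0.001). Single lists of different antibodies overlapped as much as lists of the same antibody, as the map of pairwise overlap shows. At homeostasis the mean overlap was 76.2 ± 6.76% of the shorter list over 9 pairs of different antibodies, and 75.5 ± 9.51% over 6 pairs of the same antibody. Of 5906 homeostasis regions present in 3 or more of the 6 lists, 7 were in all 3 BMI1 lists and no H2AK119ub list, and 16 were in all 3 H2AK119ub lists and no BMI1 list. All 6 homeostasis lists shared 1243 regions. Of the 3767 shared BMI1 regions, 125 (3.32%) lay on genes of tRNA or 5S ribosomal RNA. The BMI1 share depended on which lists defined an H2AK119ub region: it was 34.9% without H2AK119ub replicate 2, 34.0% without replicate 3 and 52.8% with regions required in 3 of 3 libraries. The reverse share was 35.4% without BMI1 replicate 2, and 94.1% and 93.2% without H2AK119ub replicates 2 and 3.

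**Figure D2:**
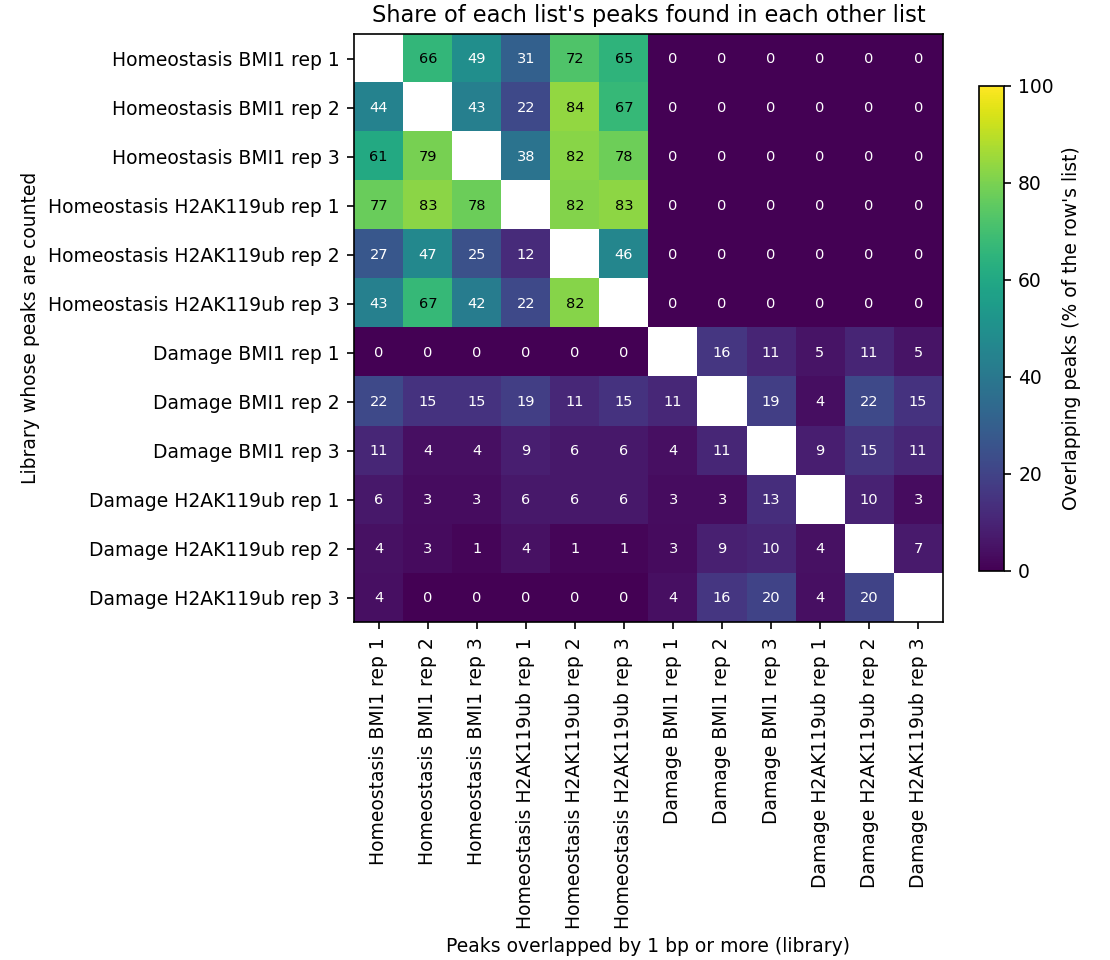
Share of the peaks of each list (vertical axis) that overlap a peak of each other list (horizontal axis), in percent and rounded to whole numbers, for all 12 libraries. Overlap was high among the 6 homeostasis lists whatever the antibody, with a mean of 76.2% of the shorter list between antibodies, and low between Damage and Homeostasis lists.

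It was then asked whether the few peaks listed after paraquat lay at sites occupied at homeostasis. For BMI1, 0 of 19, 7 of 27 and 5 of 47 peaks of the 3 Damage libraries overlapped a Homeostasis BMI1 peak, a mean of 12.2 ± 13.0%. For H2AK119ub, 2 of 31, 3 of 68 and 0 of 25 peaks did, a mean of 3.62 ± 3.30%. In 4 of the 6 lists this was above random placement (permutation p = 0.001 or 0.002), and 2 lists had no overlapping peak. The exact 95% binomial intervals, which cover counting error only, reached 17.6% for the 19 peaks of BMI1 replicate 1 and 13.7% for the 25 peaks of H2AK119ub replicate 3. The BMI1 mean was 7.59% when Homeostasis BMI1 replicate 1 was left out. Of 190 damage regions, 13 held peaks of 2 or more Damage libraries. Of these 13, 10 held peaks of both antibodies and 4 were also found in a homeostasis list. Regions in 4 or more Damage libraries, 6 of the 13, must hold both antibodies, because each antibody had 3 Damage libraries.

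Some regions recurred across Damage libraries. No sequence was used here, so they were not checked for repeats or for how uniquely reads map to them. A region in Drosha, which encodes the nuclear ribonuclease that starts microRNA processing, had a peak in 5 of 6 Damage lists, all 3 BMI1 and 2 H2AK119ub, and in no homeostasis list (chromosome 15, 12873142 to 12873343). An intergenic region of the Y chromosome also had a peak in 5 Damage lists and no homeostasis list (90819506 to 90819656), with the nearest protein-coding gene, Gm52481, 74.4 kb away. It held the widest peak of 3 Damage libraries, at 102, 127 and 150 bp. Both antibodies had 2 lists with a peak at the 5S ribosomal RNA gene n-R5s194 (chromosome 3, 4339018 to 4339134), and at the 5S pseudogene n-R5s88 inside Ephb1, which encodes an ephrin receptor (chromosome 9, 102127873 to 102127995). The latter region was also in 1 homeostasis list, Homeostasis BMI1 replicate 1. An intergenic region 18.9 kb from Ccser2 was in 4 Damage lists and no homeostasis list (chromosome 14, 36855920 to 36856034). On the X chromosome, a region 181 kb from Asmt, a gene of melatonin synthesis, was in 4 Damage lists (170859313 to 170859426) and a region 150 kb from it in 2 H2AK119ub lists (170828221 to 170828350), neither in a homeostasis list. The remaining regions found in 2 Damage libraries of an antibody were in Ptprn2, which encodes a phosphatase-like protein of secretory granules (chromosome 12, 116678371 to 116678475, 2 BMI1 lists), and 291 kb from Mgat4c (chromosome 10, 101390356 to 101390464, 2 BMI1 lists and 2 homeostasis lists). The widest peak of Damage BMI1 replicate 2 was a 112 bp peak in Rnf220, which encodes a ubiquitin ligase (chromosome 4, 117478706 to 117478817). In Damage BMI1 replicate 1 and Damage H2AK119ub replicate 3 all peaks were 101 bp wide.

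The position of peaks relative to genes was compared with random placement. At homeostasis, protein-coding genes held fewer peak centres than placement gave: 33.0 ± 0.722% (SD, n = 3) of BMI1 peaks and 32.9 ± 1.27% of H2AK119ub peaks, against 38.4% for both. This held in each of the 6 homeostasis lists (two-sided placement permutation, adjusted p = 0.004). With all annotated genes counted, the shares were 44.8 ± 1.26% and 45.2 ± 1.69% against 46.3%, and 4 of 6 lists lay below placement (permutation, adjusted p = 0.012). After damage, 51.9 ± 14.9% of BMI1 peaks and 41.9 ± 6.53% of H2AK119ub peaks were in an annotated gene. Damage exceeded homeostasis by 5.65 percentage points, less than the spread between Damage libraries (exact permutation p = 0.275 over 11 libraries with 20 or more peaks), and by 2.03 without Damage BMI1 replicate 2 and 9.28 without Damage BMI1 replicate 3. With protein-coding genes only, the difference was -3.21 percentage points (exact permutation p = 0.505). H2AK119ub peaks were in protein-coding genes in 21.2 ± 2.12% after damage, a difference from homeostasis of -11.6 percentage points, with all 3 Damage libraries below all 3 Homeostasis libraries (exact permutation p = 0.1, the smallest possible). Peaks in Igh, which is annotated but not as protein-coding, made up 8 to 19.1% of these Damage lists and 0.0931 to 0.15% of the Homeostasis lists. BMI1 peaks differed by 5.21 percentage points over 2 Damage libraries (exact permutation p = 0.7). The difference between antibodies, tested after the data were seen, did not pass (16.8 percentage points, exact permutation p = 0.06). Promoters, exons and introns were not separated, because the annotation used gives gene boundaries only.

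The genes with the most homeostasis peaks were long ones. A peak in the gene body or within 5 kb of it was present in all 3 libraries for 973 protein-coding genes with BMI1 and 640 with H2AK119ub, of 21887 genes, and 559 were common to both. Of genes in the longest of 10 length classes, 33.7% had a BMI1 peak in 2 or more libraries and 41.8% an H2AK119ub peak, against 1.87% and 2.28% in the shortest class. The 25 leading genes were ranked by the mean over libraries of their percentile in summed peak width. Their median length was 1098 kb for BMI1 and 1020 kb for H2AK119ub, against 17.2 kb for all protein-coding genes. The rankings had 14 genes in common, among them Rbfox1, Ppargc1a, Sgcz, Ctnna3, Gpc6, Robo1, Dcc, Gpc5, Lrp1b, Inpp4b and Ntm. Rbfox1, a regulator of splicing, held 7.33 ± 2.52 BMI1 peaks and 9.0 ± 6.0 H2AK119ub peaks per library (chromosome 16, 5884793 to 7412480). Ppargc1a, the coactivator that drives mitochondrial biogenesis, held 6.33 ± 1.53 and 7.0 ± 3.0 (chromosome 5, 51454249 to 52115853). Sgcz, a sarcoglycan of the dystrophin complex, held 6.33 ± 1.53 and 7.0 ± 2.65 (chromosome 8, 37517840 to 38661705). Ctnna3, an alpha-catenin of the cardiac intercalated disc, held 5.67 ± 2.08 and 7.67 ± 6.03, the latter 4.5 without H2AK119ub replicate 2 (chromosome 10, 63430098 to 65003667), and Robo1, a receptor for Slit guidance proteins, held 6.33 ± 2.08 and 6.0 ± 3.61 (chromosome 16, 72027518 to 73047491). Of the 40 peaks of Ctnna3 over the 6 lists, 6 lay on a tRNA gene.

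Gene length was then taken into account. Against the number of peaks placed by chance in a span of the same length, the 25 leading BMI1 genes held 1.05 to 6.0 times as many (median 2.22) and the 25 leading H2AK119ub genes 1.12 to 3.88 times as many (median 2.02). The genes were picked for their mean percentile in summed peak width, so ratios above 1 follow in part from the selection. A density test over all 21887 genes, chosen after the data were seen, called 0 for either antibody (241 and 236 at an unadjusted p under 0.05). The highest BMI1 ratio was that of Adam12, a metalloprotease gene, with 4.0 ± 1.0 peaks (chromosome 7, 133883199 to 134225097). The highest H2AK119ub ratio was that of Hhat, which encodes the acyltransferase of Hedgehog proteins, with 3 peaks in each of the 6 lists (chromosome 1, 192512825 to 192771219). Only in the BMI1 ranking were Lsamp, Macrod2, Marchf1, Tenm2, Celf2, Lrrc4c, Ctnna2, Opcml, Ptprd, Cntnap5b and Adam12. All but Marchf1 and Adam12 held 0 or 1 peak in Homeostasis H2AK119ub replicate 1, the shortest homeostasis list. The ranking averages over libraries and requires a peak in all 3, so low counts in that list lower a gene's place. Lsamp held 8.33 ± 7.64 H2AK119ub peaks per library and Macrod2 7.67 ± 6.51, against 3 for Hhat. The H2AK119ub ranking alone named Hhat, Galnt17, Auts2, Csgalnact1, Rora, Asic2, Immp2l, Npas3, Pde4d, Nrg3 and Prkg1; whether the rankings differ was not tested. Of the 36 genes in either ranking, 33 had no peak in any Damage list, and Ctnna2, Nrg3 and Prkg1 had a single peak in 1 Damage list each. Cdkn2a, the INK4a and ARF locus repressed by BMI1 in many cell types (chromosome 4, 89274473 to 89294619), and Bmi1 itself (chromosome 2, 18677018 to 18686629) had no peak in any of the 12 lists. Chance gave 0.0548 BMI1 peaks and 0.0802 H2AK119ub peaks per homeostasis library at Cdkn2a, so a count of 0 there does not separate it from other genes of its length.

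Gene lists fixed in advance were then examined at homeostasis, counting members with a peak in 2 or more of 3 libraries. Endothelial genes had 6 of 22 members with a BMI1 peak (2.53 in random lists matched on gene length) and 6 with an H2AK119ub peak (3.28). Among them were Emcn, encoding the endothelial sialomucin endomucin, with 2.0 ± 1.0 peaks for each antibody (chromosome 3, 137341062 to 137431069), and Flt1, a receptor for vascular endothelial growth factor, with 1 peak in each of the 6 lists. Smooth muscle genes had 3 of 12 members with a BMI1 peak (1.42 in random lists) and 5 with an H2AK119ub peak (1.81). They included Mylk, encoding myosin light chain kinase, with 1.67 ± 0.577 and 1.33 ± 0.577 peaks, and Tpm2, encoding beta-tropomyosin, with 1 peak in each of the 6 lists (chromosome 4, 43513726 to 43523583). Only these 2 lists had an unadjusted permutation p under 0.05, endothelial genes with BMI1 (p = 0.0406) and smooth muscle genes with H2AK119ub (p = 0.0224), and neither passed adjustment over the 28 tests (adjusted p = 0.568 for both). None of the 14 lists passed for either antibody.

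No other list had an unadjusted permutation p under 0.05, with members counted for BMI1 and H2AK119ub and the means of the random lists given in that order. HOX cluster genes had 1 of 39 members with a peak for each antibody, Hoxb1 (1.17 and 1.51 in random lists). Developmental transcription factors outside HOX had 4 of 50 for each antibody (2.04 and 2.66), among them Olig1, Pax7 and En2, and developmental signalling genes had 2 of 41 for each (2.95 and 3.86), among them the BMP antagonist gene Grem1. Cardiac and mesoderm transcription factors had 2 of 25 for each (1.47 and 1.96), Mef2c and Wt1. Cardiomyocyte genes had 4 and 3 of 23 (2.27 and 2.91), among them Ryr2, the calcium release channel of the sarcoplasmic reticulum, and the potassium channel gene Kcnq1. Fibroblast genes had 3 and 2 of 21 (1.96 and 2.54), with Pdgfra and Dcn in both counts. Blood cell genes had 4 and 5 of 23 (2.39 and 3.03). Among them, the Fc receptor gene Fcgr3, had 13 peaks over the 6 lists, all 13 of them on tRNA genes beside or inside it (chromosome 1, 171051169 to 171065915). Antioxidant genes had 2 of 35 for each antibody (1.83 and 2.49), both of which encode enzymes that remove reactive oxygen species. These were Sod3, the extracellular superoxide dismutase, with 1.33 ± 0.577 and 2.0 ± 1.0 peaks (chromosome 5, 52363804 to 52369738), and Cat, catalase, with 1 BMI1 peak in each library and H2AK119ub peaks in 2 of 3 (chromosome 2, 103453904 to 103485153). Genes of p53 and the DNA damage response had 1 of 28 for each (1.84 and 2.49), Prkdc, which encodes the catalytic subunit of DNA-dependent protein kinase. Cell cycle regulators had 1 of 25 for each (1.67 and 2.16), Mycn, with 1 peak in each of the 6 lists (chromosome 12, 12936093 to 12941836). Polycomb subunit genes had 2 and 3 of 27 (2.66 and 3.46), among them Jarid2 with 2.33 ± 0.577 and 1.67 ± 0.577 peaks (chromosome 13, 44730774 to 44921643), and Ezh2, the methyltransferase of Polycomb repressive complex 2. Housekeeping genes had 0 of 20 (0.662 and 0.855). When each peak was instead given to the gene with the nearest end within 100 kb, 3 tests passed. By permutation of list membership, these were developmental transcription factors with BMI1 (12 members against 4.34, adjusted p = 0.0131) and with H2AK119ub (18 against 5.73, adjusted p = 0.0056), and cardiac and mesoderm factors with H2AK119ub (11 against 3.57, adjusted p = 0.0131). None passed once the random lists were matched on the span over which a gene is the nearest (smallest permutation p after adjustment, 0.246), a matching chosen after the data were seen.

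**Figure D3:**
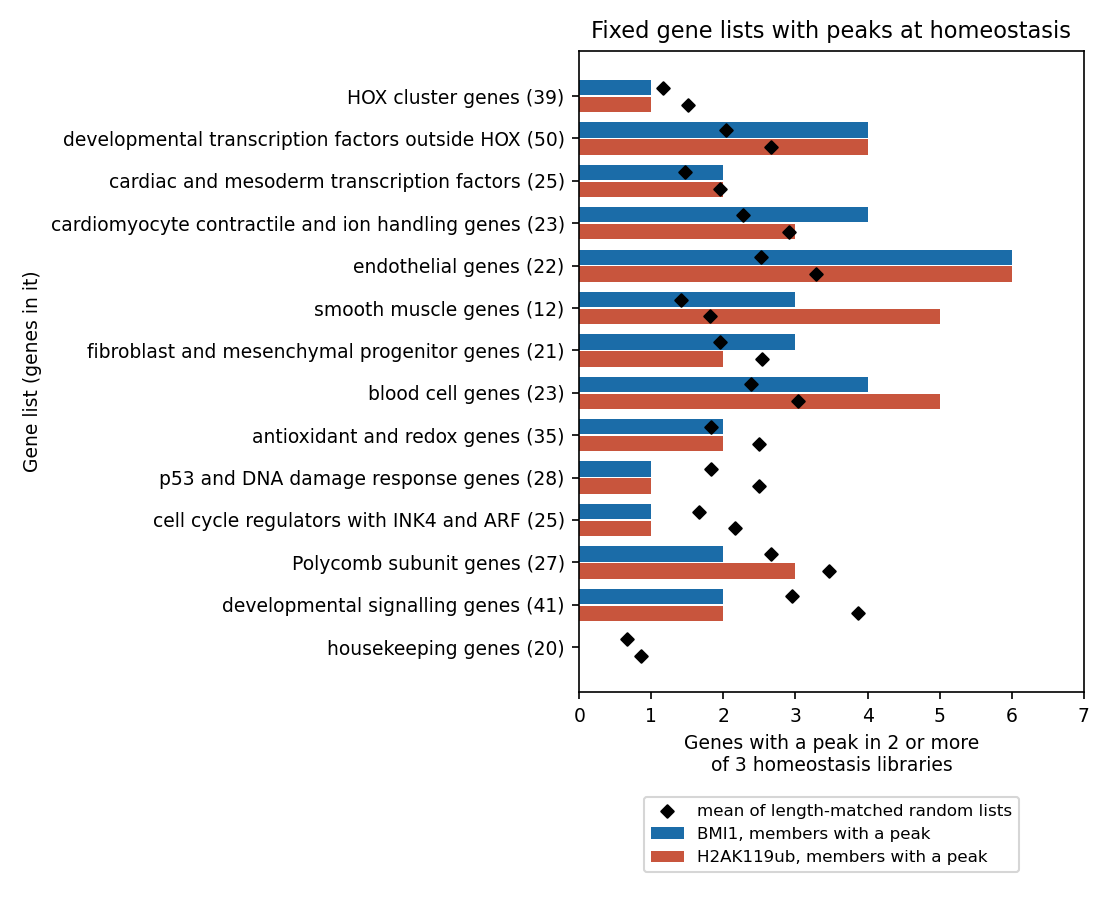
Members of each fixed gene list with a peak in 2 or more of 3 homeostasis libraries (bars, horizontal axis, number of genes) for BMI1 and H2AK119ub, with the mean of 10000 random lists matched on gene length (diamonds). Endothelial genes with BMI1 had 6 members against 2.53, and no list passed the adjusted test.

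The same lists were compared between treatments by the number of members with a peak per library. In 12 of 14 lists fewer members had a peak after damage (exact permutation test within antibody, adjusted p = 0.00875 for 8 lists and 0.0233 for 4). These tests add nothing to the fall in total peak number: a Damage library had a peak at 5 to 21 of the 21887 protein-coding genes (0.0228 to 0.0959%), so lists of 12 to 50 genes would hold about 0 of them whatever their kind. Endothelial genes had 5.33 ± 1.53 members with a peak for BMI1 and 6.33 ± 3.51 for H2AK119ub at homeostasis (n = 3 each) and 0 in every Damage library. Smooth muscle genes had 3.33 ± 1.53 and 4.33 ± 2.08 members at homeostasis, blood cell genes 4.0 ± 1.0 and 3.67 ± 2.31, and antioxidant genes 2.33 ± 0.577 and 2.33 ± 1.53, again with 0 in every Damage library. The sole list member with a peak after damage was Rb1, the retinoblastoma gene of the cell cycle list, in Damage H2AK119ub replicate 3 (chromosome 14, 73280645 to 73280745). HOX cluster genes did not pass (exact permutation, adjusted p = 0.0862), and no housekeeping gene had a peak in any list. The number of passing lists was 7 when only peaks within 5 kb of a gene end were counted.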

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

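The versions without peaks in Igh and on tRNA and 5S genes, the alternatives for damage regions recurring over all 6 lists and the span-matched random lists were chosen only after the result was seen. Over 22 results, 181 of 200 alternatives gave the same outcome and 19 did not. The same outcome meant the same direction and side of the threshold. For values without a test it meant staying within the spread or within 1.5 times. Alternatives for peak number within a single antibody could not cross the threshold, since their exact permutation p was at least 0.1. Their agreement covers direction only. Of 608 alternatives for single named genes, 1 moved: Fcgr3 with H2AK119ub fell to 1.67 peaks with peaks within 1 kb merged. With all libraries kept, folds between treatments lay from 178 to 199 for BMI1, from 151 to 186 for H2AK119ub and from 164 to 189 for both antibodies. Leaving out a library gave 146 to 226 for BMI1, 101 to 261 for H2AK119ub, 134 to 216 for both (exact permutation p = 0.005 each time), and 105 to 170 for covered length. The ratio of BMI1 to H2AK119ub folds ranged from 0.685 to 1.78 with a library left out, and was 0.959 without Damage BMI1 replicate 1, 0.878 without Damage H2AK119ub replicate 2, 0.991 without Homeostasis BMI1 replicate 2 and 0.685 without Homeostasis H2AK119ub replicate 1; it was never past the threshold. Consensus in 3 of 3 libraries gave 2 and 1 regions after damage and 2295 and 1567 at homeostasis, by the stricter rule itself. With a library left out and both others required, the counts ranged from 2 to 5 for damage BMI1, 1 to 5 for damage H2AK119ub, 2479 to 3319 for homeostasis BMI1 and 1630 to 6166 for homeostasis H2AK119ub, lowest without BMI1 replicate 2 (damage and homeostasis), Damage H2AK119ub replicate 2 and Homeostasis H2AK119ub replicate 3; they were 3 without Damage BMI1 or H2AK119ub replicate 3 and 1659 without Homeostasis H2AK119ub replicate 2. The location difference was -3.21 percentage points with protein-coding genes only. Igh, which is annotated but not as a protein-coding gene, held 10.3% of peaks per Damage list and 0.149% per Homeostasis list. Peaks there count in the first measure and not in the second. How far they account for the change was not tested. At homeostasis 3 gene-list tests passed with the nearest gene within 100 kb, and 0 did once the span was matched. Between treatments 7 lists passed within 5 kb of gene ends; the cause was not tested. Treatment groups share replicate numbers, but the deviations of same-numbered Damage and Homeostasis libraries over 17487 regions correlated at -0.0363 to 0.00527 in 6 pairs, and 1 of 6 Damage libraries correlated best with its own number. With the replicate block, 0 of 14 lists passed in an exact sign-flip test over 6 pairs, whose smallest p is 0.03125 before adjustment; the cause was not tested. The fold over both antibodies stayed at 165 (exact p = 0.03125). Without Igh, tRNA and 5S peaks the fold was 189. Alternatives filtering on the score, which is constant, or using promoter windows were not run. Depth is unknown, so none of these results is scaled for it.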

Other observations

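Except for the test on olfactory and vomeronasal receptor genes, the tests in this part were chosen only after the result was seen. Of 8 gene classes counted, tRNA and 5S ribosomal RNA genes, both transcribed by RNA polymerase III, held the most homeostasis peaks relative to chance. The 6 homeostasis lists held 603 peaks on tRNA genes, where 1.05 were placed by chance, and 218 on 5S ribosomal RNA genes, where 0.22 were (placement permutation p = 0.001 for each, the smallest possible). Genes of small nuclear RNA held 55 peaks against 3.20 by chance (placement permutation p = 0.001), while olfactory and vomeronasal receptor genes held 319 against 330 (p = 0.726). Of 408 tRNA genes, 144 (35.3%) had a peak in some homeostasis list, 88 had one in 2 or more libraries of both antibodies, and 59 had one in all 6. Of 69 5S genes, 43 had a peak, and the 41 genes of the cluster on chromosome 8 (123538784 to 123622046) included 32 with peaks of both antibodies and 0 with a damage peak. The tRNA genes were not hit evenly by amino acid. Both antibodies marked 6 of 7 genes for phenylalanine, 12 of 16 for proline and 9 of 16 for aspartate, but 0 of 83 genes for histidine, isoleucine, asparagine, glutamine, threonine and tyrosine together (permutation p = 0.0001, the smallest that 10000 permutations give; genes of an isotype share sequence and are not independent). Other genes of this polymerase (Rn7sk, Rmrp, Rpph1, Rnu6, Rny1 and Rny3) had a peak in 0 of 6 cases (Fisher's exact p = 0.0964 against tRNA genes). In the damage lists, 11 of 217 peaks (5.07%) lay on tRNA or 5S genes, at 4 sites. The mean share per list was 5.25 ± 5.58% after damage and 2.82 ± 1.81% at homeostasis (n = 6 each, exact permutation p = 0.405).

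Chromosome ends also held homeostasis peaks. Beyond the last annotated gene, each homeostasis list had 13 to 22 peaks on 12 to 18 of 21 chromosomes, 113 of 39615 peaks (0.285%) over the 6 lists. The damage lists had 8 of 217 peaks there (3.69%), all on the X chromosome. All 8 were in the 3 regions near Asmt given below, so the damage share rests on these sites alone. The mean share per list was 3.48 ± 3.57% after damage and 0.369 ± 0.178% at homeostasis (n = 6 each, exact permutation p = 0.05). No protein-coding gene stood out by peak density at homeostasis: 0 of 21887 genes passed adjustment for either antibody. At an unadjusted p under 0.05 in this density test there were 241 for BMI1 and 236 for H2AK119ub. In simulation the test called 79 of 200 genes of 200 kb or more with added regions. The 3 damage regions near Asmt that held those 8 peaks (X chromosome, 170815303 to 170859426), like the recurrent region on the Y chromosome, lay in or beside the pseudoautosomal part that both sex chromosomes share.

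The first pattern was the drop to 19 to 68 peaks in the damage lists. If the same sites had been called from fewer reads, the peaks left should lie at homeostasis sites, but the highest share that did was 25.9%, below the lowest share of any homeostasis list found in its own replicates (46.3%). Of the recurrent damage regions, 76.9% (10 of 13) held peaks of both antibodies, against 78.5% with antibody labels drawn at random. Of these 13 regions, 6 had peaks in 4 or more Damage lists. Such a region must hold both antibodies, because neither antibody has that many Damage lists. The remaining regions are too few to decide whether sites were called whatever the antibody. Loss of occupancy after paraquat, reads so few that mostly background was called, and different calling settings stay open, since depth and settings are unknown and may differ between the treatments.

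The second pattern was that BMI1 and H2AK119ub shared their homeostasis sites. Developmental genes known as Polycomb targets were counted only as 130 genes of the fixed HOX, developmental transcription factor and developmental signalling lists. Within 5 kb of them lay 0.133% of 3758 shared regions (upper exact 95% limit 0.310%), against 0.144% by chance. Shared regions were thus not detectably more frequent at these genes than by chance. So few genes could hold only a small share, and other Polycomb targets were not counted. Mean overlap within an antibody minus that between antibodies was -0.692 percentage points (SD of pairs 7.65), which sites called whatever the antibody and true colocalisation both predict; the highest other value was 4.27, and the 10 splits of the 6 lists are too few for a share under 0.05. Salmon sperm DNA from the beads, aligned to mouse sequence conserved across vertebrates, was predicted to raise the share in protein-coding genes. That share was 32.9% against 38.4% by placement. The prediction rests on exons, which the annotation does not give. Whole gene bodies were counted instead, so the share cannot decide on this source. At tRNA and 5S genes that source cannot be told apart from binding. Of the 11 damage peaks there, 27.3% (3 of 11, exact 95% interval 6.02 to 61.0%) were on genes with a peak in 2 or more homeostasis lists. The 11 peaks lay at only 4 sites, too few to decide, and the interval takes repeats of a site as independent.

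The third pattern was a cluster of damage peaks in Igh, the immunoglobulin heavy chain locus (chromosome 12, 113258768 to 116009954). It held 28 of 217 damage peaks (12.9%) in 5 of 6 lists, where the highest of 1000 random placements was 3, and its share per list was 10.3 ± 7.59% after damage and 0.149 ± 0.0337% at homeostasis (n = 6 each, exact permutation p = 0.02). Without Damage H2AK119ub replicate 2 it was 15 of 149, and the light chain and T cell receptor loci had 0 damage peaks. By number, the 6 Homeostasis lists held 56 peaks in Igh, against 40.2 by chance, so the higher damage share was not a higher count. Rearranged DNA of B cells cannot be told apart as a source: 17.9% of the 28 (exact 95% interval 6.06 to 36.9%) lay in the part with the constant regions, toward which rearrangement deletes DNA, so such DNA in the input would raise that share and in the reads would lower it, although sorting against CD45 would remove B cells. Reads shared between near-identical copies cannot be told apart either. Olfactory and vomeronasal receptor genes held 2 damage peaks against 1.16 by chance, 1.73 times as many. The limit set in advance against this source, a count of at most 2 times chance, was met. The exact 95% Poisson interval of the count, 0.242 to 7.22, also covers larger excesses, so so few peaks cannot decide. Pseudogenes held 8 against 2.47 (placement permutation p = 0.009). This class holds n-R5s88 by its annotation, whose peaks in 4 Damage lists count here and again among the 5S genes. Placement took repeats of a site as separate peaks in both classes. The 5S genes held 8 against 0.001 (placement permutation p = 0.001) at 2 sites, with 0 in the cluster of 41 copies. An effect of paraquat was not tested.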
